A study of Mus musculus with 16 samples.

How the data were processed

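Total RNA from gastrocnemius muscle of 16 mice was hybridised to Illumina bead arrays, 1 array per animal. The labels place the animals in 4 groups: 4 wild-type mice given vehicle, 5 wild-type mice given the histone deacetylase inhibitor 4b, 4 N17182Q transgenic mice given vehicle and 3 transgenic mice given 4b. Each label carries its own animal number, so the arrays were treated as separate animals; replicate numbers follow the order of deposit and pair no animals. Dose, duration, age and sex are not given in the sources used here.

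The non-normalized table holds 1 probe intensity per probe and array on a linear scale, as deposited, and per the file headers no normalization had been applied. Intensities ran from 81.2 to 44501. The deposited table also gives a detection p-value per probe and array, per the file headers, in 798 steps, and the comparison with background that made it is not given in the sources used here. A second deposited table holds the authors' log2 values. Set against the intensities of its own array, each of its columns kept the order of the probes (lowest Spearman correlation 1), the sorted columns differed by at most 0.00058, and every column had a median of 7.11. These values matched log2 followed by quantile normalization without background correction, with no centring of genes; the method itself is not given in the sources used here.

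For the main results the background was corrected with limma 3.58.1 in R 4.3.3 by the normexp model, with the background estimated from the detection p-values and an offset of 16, followed by quantile normalization and log2. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none in the platform annotation. Of these, 23962 matched the reference table (assembly GRCm38.p6, used for names and neighbours only) by gene identifier, and the match changed 0 symbols. Probes with a detection p-value under 0.05 on at least 3 arrays were kept, which left 13706. For each gene the probe with the highest mean stood for it, and 2448 genes had over 1 such probe. This left 10295 rows, 9521 with a symbol and 774 without. Columns assigned to no sample numbered 0.

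A limma model with 4 group means was fitted to all 16 arrays (residual degrees of freedom 12, prior degrees of freedom 3.09). Contrasts were tested two-sided with moderated variances and Benjamini-Hochberg adjustment over all rows, and a gene was called at an adjusted p under 0.05. Quantile normalization forces equal distributions, so a change of most genes in 1 direction cannot be measured. The offset added to the corrected intensities compresses the change of dim probes. Where no array of a group was above background, the change is given as "at least N-fold": the brighter group's mean against, per array, the higher of the probe's own value and the lowest signal among detected probes. Precision was set by the number of animals; the median standard error of a log2 difference was 0.217 for genotype with vehicle, 0.206 for 4b in wild-type mice, 0.235 for 4b in transgenic mice and 0.224 for genotype with 4b. Between 42.7% and 50.3% of probes were detected per array.

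Gene lists for muscle, polyglutamine disease, histone deacetylase inhibition and other cell types were fixed before the data were examined, and the 33 of 34 with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted within a contrast. Camera with an estimated correlation and fry were run beside it. A list score is the mean, over the list's genes, of an array's difference from the mean of wild-type mice given vehicle. Lists of lymphocytes, of lymph node vessels and stroma, and of macrophages were written after the data were seen. Single measures were compared with exact permutation tests.

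Genes were named by a rule fixed before the data were examined. In a comparison with over 20 calls these are the 12 largest rises and 12 largest falls among called genes whose arrays do not overlap between groups, leaving out RIKEN, LOC and Gm identifiers; with 20 or fewer calls, every called gene; with 0 calls, the 5 smallest p-values in each direction. List members are the called ones with the smallest p, at most 4, or otherwise 2 with the smallest p. Htt, Prnp, Xist, Ddx3y, Hdac1 and Hdac3 are always given where tested; Ddx3y was not among the tested genes.

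The fit was tested on simulated data with the real genes' means and spreads, 200 of 10295 genes changed. Noise was drawn independently for each gene with the same spread in every group. The shares below therefore do not cover correlated genes or a wider spread among transgenic animals. For transgenic against wild-type mice given vehicle, 7.46% of genes changed by 0.5 log2 units were recovered, 53.7% of those changed by 1 and 89.4% of those changed by 2, with 6 false calls among 106. For 4b in wild-type mice the shares were 10.4%, 62.7% and 95.5%, and for 4b in transgenic mice 4.48%, 41.8% and 90.9%. For genotype in mice given 4b they were 10.4%, 65.7% and 80.3%. Alternatives fixed before the data were examined covered background correction, an offset of 50, median scaling, cyclic loess, the authors' values, 2 other filters, all detected probes, only the groups compared, an intensity trend with a robust prior, array weights, an ordinary per-gene test without moderation, an assumed chip, omission of the 2 animals numbered in 3 digits and omission of each array. In comparisons of 2 groups, the test without moderation also took its variance from those groups alone. The files name no chip, so the chip was assumed from the deposited order. Covariates for sex, lymphocyte and adipocyte scores and detected share, and omission of arrays with high lymphocyte scores, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.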

Results

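Gene expression was measured in gastrocnemius muscle of B6C3F1/J mice that were wild type or carried the N17182Q transgene, which drives an N-terminal fragment of mutant huntingtin with an expanded polyglutamine stretch from a prion promoter. Mice received vehicle or 4b, an inhibitor of histone deacetylases, and the design asks how 4b acts on muscle expression in each genotype. There were 4 wild-type mice given vehicle, 5 wild-type mice given 4b, 4 transgenic mice given vehicle and 3 transgenic mice given 4b. The share of probes detected was 45.1% ± 2.59 (SD, n = 4), 46.2% ± 1.94 (SD, n = 5), 47.2% ± 2.74 (SD, n = 4) and 46.4% ± 0.667 (SD, n = 3) in these groups. Pairs of arrays correlated at 0.901 to 0.985 over the tested genes. The Y-linked Eif2s3y and the X-inactivation transcript Xist showed males and females in every group: 2 of 4, 2 of 5, 3 of 4 and 1 of 3 animals were male in the order above. Xist was not called in any comparison (adjusted p = 0.643 for genotype in mice given vehicle, limma).

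Prnp, the prion protein gene, lay between 13.99 and 15.09 log2 units in the 7 transgenic arrays and between 13.32 and 13.77 in the 9 wild-type arrays, a difference of 0.87 (exact permutation test over 11440 divisions, two-sided p = 8.7e-05, the smallest it can give). In transgenic mice it was 14.65 ± 0.34 (SD, n = 4) with vehicle and 14.03 ± 0.07 (SD, n = 3) with 4b, a difference of -0.62 ± 0.18 (SE) that did not pass (limma, adjusted p = 0.161). The Htt probe was dim, detected on 9 arrays, and differed by -0.24 between genotypes over all arrays (exact permutation p = 0.0969). By exact permutation within treatments the genotype difference was -0.28 (exact permutation p = 0.0301), and within genotypes the 4b difference was -0.30 (exact permutation p = 0.0195), while limma called neither. It lies in the mouse gene and checks nothing about the transgene. Hdac3 was lower in transgenic mice averaged over treatments, by 0.46 log2 units on the fitted scale (-0.46 ± 0.11 SE, limma adjusted p = 0.00467), and Hdac1 differed by -0.21 ± 0.14 (SE) without passing (adjusted p = 0.273). The Hdac3 call was lost under 2 of 35 alternatives, median scaling and omission of 6 arrays of high lymphocyte score. Its change ran from -0.54 to -0.26 over the alternatives.

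Muscle of transgenic mice given vehicle had far more sarcolipin (Sln), an inhibitor of the sarcoplasmic calcium pump, than muscle of wild-type mice given vehicle: 13.69 ± 0.44 (SD, n = 4) against 8.29 ± 0.87 (SD, n = 4), a 42.1-fold rise (log2 5.40 ± 0.44 SE, limma adjusted p = 2.74e-05). The slow fibre gene Casq2 and the endplate genes Chrna1 and Musk rose too, and the collagen gene Col1a1, the fast myosin gene Myh4 and the spermine oxidase gene Smox fell. In all, 546 of 10295 genes were called, 246 higher and 300 lower in transgenic mice, and 266 of these changed over 2-fold. Median scaling in place of quantile normalization moved the median of all genes from 0.01 to 0.12 and gave 528 higher and 199 lower.

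The largest rises after Sln were Kcne1l (12.1-fold), the GTPase gene Rab15 (7.26-fold), the calsequestrin gene of slow and cardiac muscle Casq2 (6.22-fold), the prolyl hydroxylase gene Egln3 (4.69-fold), the small heat shock protein gene Hspb7 (4.61-fold), Ankrd2 (4.54-fold), the acetylcholine receptor subunit gene Chrna1 (4.39-fold), Smtnl1 (4.18-fold), Chrna9 (4.07-fold) and the perinatal myosin gene Myh8 (4.03-fold). Myl6b was not above background on any wild-type vehicle array and was at least 3.05-fold higher in transgenic mice. Among the falls, Syne1 was not above background on any of the 4 transgenic arrays and was at least 7.32-fold lower, but its other detected probe moved the opposite way. Fgfbp1 was likewise at least 5.35-fold lower. The potassium channel subunit gene Kcnab1 was 11.4-fold lower, Smox 11.2-fold, the type I collagen gene Col1a1 8.57-fold, the mitochondrial gene Gdap1 8.34-fold, Tigar 6.12-fold, Emid1 5.96-fold, Tmem266 5.84-fold, Nrep 5.79-fold, Col3a1 5.28-fold and Cyp2f2 5.16-fold. Adjusted p in limma ran from 2.74e-05 for Sln to 0.0471 for Cyp2f2, and the calls of Col3a1 and Cyp2f2 were lost under 22 and 24 of 35 alternatives, the authors' values among them. Calls were also lost under 8 of 35 alternatives for Tigar and 5 of 35 for Tmem266. For Nrep and Ankrd2 they were lost under 5 of 36 and for Myh8 under 2 of 36. Each of these included the omission of a single array. Kcne1l was detected on 1 of 4 wild-type vehicle arrays, and Tigar, Col3a1 and Tmem266 on 1, 1 and 2 of 4 transgenic vehicle arrays, so the size of these changes rests on how background was treated. Without background correction their log2 changes were 1.995, -1.35, -1.17 and -1.30 in this order, against 3.59, -2.61, -2.40 and -2.55. Over the alternatives the changes of Chrna9, Emid1, Cyp2f2 and Col1a1 were as small as 1.05, -1.42, -1.37 and -2.06, against 2.02, -2.575, -2.37 and -3.10.

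**Figure D1:**
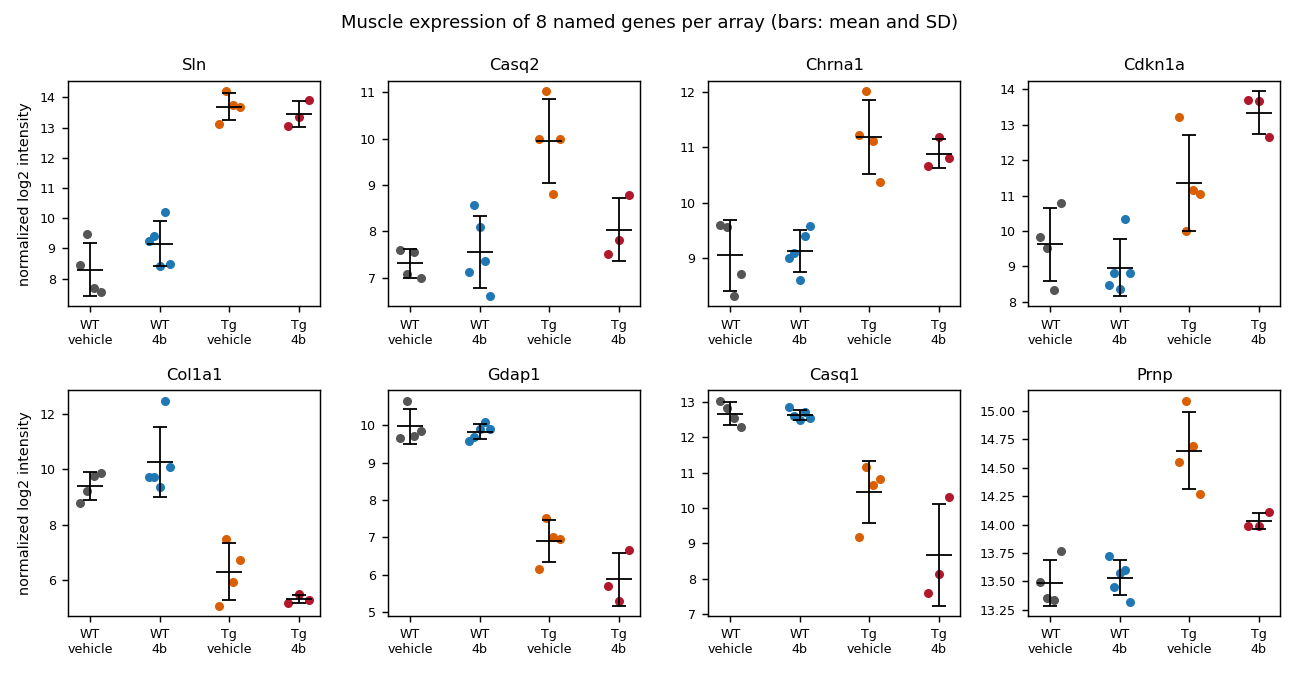
Normalized log2 intensity (y axis) of 8 named genes on each array, by group (x axis); points are arrays and bars the mean and SD. Sln averaged 13.69 in transgenic and 8.29 in wild-type mice given vehicle, and Prnp lay at 13.99 or above on every transgenic array and at 13.77 or below on every wild-type array.

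By gene lists, 5 of 27 genes of PGC-1 and fatty acid oxidation rose and 0 fell (11 rose when adjusted over the list alone). Among them were the acyl-CoA dehydrogenase genes Acadl (1.33 ± 0.22 SE) and Acadvl (0.89 ± 0.16 SE), with Etfdh and Slc25a20 (camera adjusted p = 4.76e-07, and adjusted p = 0.457 with an estimated correlation). Of 12 slow fibre genes, 4 rose (4 when adjusted over the list alone). These were Sln, Casq2, Fhl2 and Myoz2 (camera adjusted p = 3.59e-06, and adjusted p = 0.457 with an estimated correlation). The slow myosin gene Myh7, given here outside the naming rule, overlapped between the groups. It ran from 6.79 to 9.98 on transgenic and from 6.15 to 8.57 on wild-type vehicle arrays. Of 18 genes of the neuromuscular junction and denervation response, 4 rose (6 adjusted over the list alone). These were Chrna1, Gadd45a, Runx1 and Musk (camera adjusted p = 0.00137, and adjusted p = 0.457 with an estimated correlation). Of 23 genes of extracellular matrix and fibroblasts, 8 fell (10 adjusted over the list alone). They were led by Col1a1, Col15a1, Col6a2 and the collagen chaperone gene Serpinh1 (camera adjusted p = 1.93e-05, and adjusted p = 0.593 with an estimated correlation). Of 17 fast fibre genes, 5 fell (5 adjusted over the list alone). They included Gpd1, Myh4, Casq1 and Myoz1 (camera adjusted p = 0.00153, and adjusted p = 0.457 with an estimated correlation).

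In the glycolysis and glycogen list, 2 of 19 genes, Phka1 and Pgm1, fell and the glucose transporter gene Slc2a1 rose (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00122, and adjusted p = 0.593 with an estimated correlation). Of 18 genes of excitation-contraction coupling, Camk2a and the junctophilin gene Jph2 fell, 2 in all (2 adjusted over the list alone, camera adjusted p = 0.00137, and adjusted p = 0.593 with an estimated correlation). The list of muscle atrophy and protein breakdown shifted up, with 5 of 26 genes higher and 2 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0184, and adjusted p = 0.593 with an estimated correlation). Eif4ebp1, Foxo1 and Mt1 rose and Ube2b fell. The glucocorticoid response list shifted up, with 3 of 16 genes higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.688 with an estimated correlation). Foxo1, Mt1 and Ddit4 rose and Sgk1 fell. The glucocorticoid call was lost under 9 of 34 alternatives, with an adjusted p of up to 0.215 without Tg_vehicle replicate 1, whose score was 1.40 (others 0.12 to 0.87). It was also lost without Tg_vehicle replicate 3 (0.082) and WT_vehicle replicates 1 (0.0511), 2 (0.062) and 3 (0.0732), and the atrophy call was lost without Tg_vehicle replicate 1 (0.167) or 3 (0.0643). The 26 cytosolic ribosomal protein genes shifted up by a median of 0.16 with 0 called (0 adjusted over the list alone, camera adjusted p = 0.00256, and adjusted p = 0.593 with an estimated correlation). Rpl19 was at 0.58 ± 0.17 (SE) and Rps19 at 0.33 ± 0.15 (SE), neither passing, and the call was lost under 3 of 34 alternatives, among them without Tg_vehicle replicate 4 (0.0585). No list held with an estimated correlation in any comparison, and fry called 6 of 33 lists here, 2 of them not called by camera. These were the p53 response (fry adjusted p = 0.00103) and the histone and class I histone deacetylase inhibitor response genes (fry adjusted p = 0.00898). Adipocyte markers had a median of -0.34 and leukocyte markers 0.04, and neither list was called (camera adjusted p = 0.641 and 0.968).

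The count of 546 fell to 0 in an ordinary per-gene test without moderation of the variance, which also used only these 8 arrays. It fell to 124 with moderation and only these 8 arrays in the fit, and to 222 without the 2 animals numbered in 3 digits. It rose to 880 with array weights and to 1049 with the share of detected probes as a covariate, and was 254, 243 and 183 without WT_vehicle replicates 1, 2 and 3, and 175 and 311 without Tg_vehicle replicates 1 and 3.

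**Figure D2:**
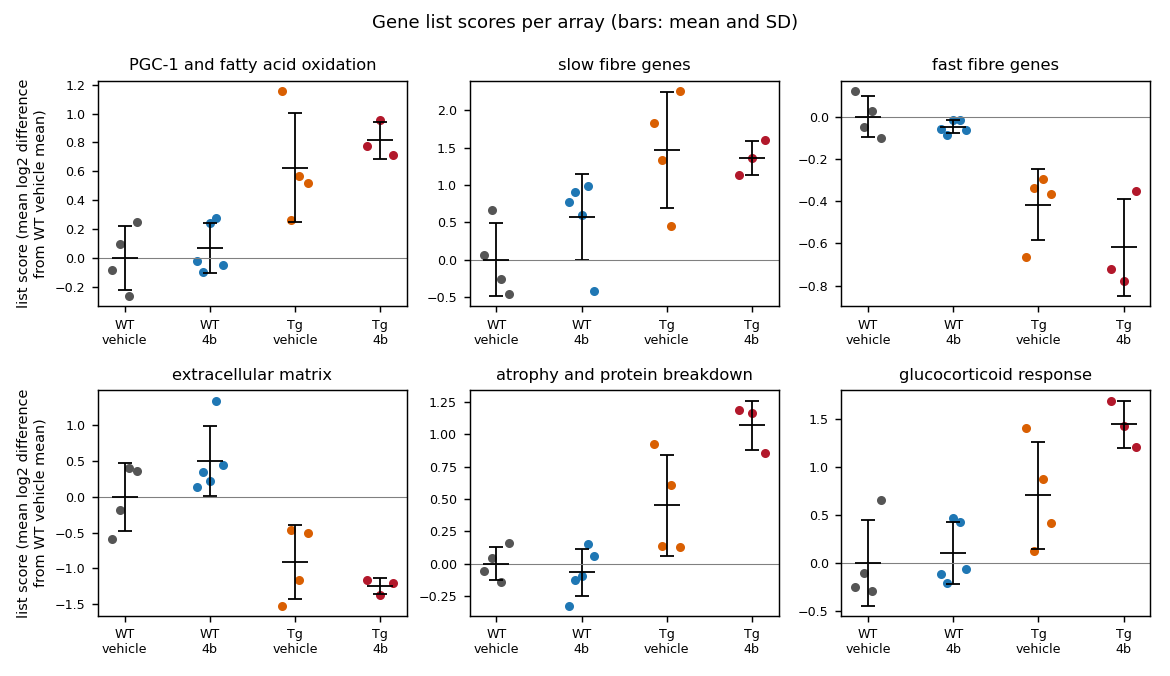
Score of 6 gene lists on each array (y axis, mean log2 difference from the mean of wild-type mice given vehicle) by group (x axis); points are arrays and bars the mean and SD. The extracellular matrix score lay below 0 on all 7 transgenic arrays, and the atrophy score averaged 1.07 in transgenic mice given 4b and 0.45 in those given vehicle.

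4b called 0 genes in wild-type mice (5 arrays with 4b against 4 with vehicle). At an unadjusted p under 0.05, limma gave 275 genes where chance alone gives 515 on average. Genes move together and the spread was pooled over all groups, so the count can lie far from this average. The ordinary test without moderation also called 0. The genes with the smallest p that were higher with 4b, none passing, were Kcnk2 (0.57 ± 0.16 SE), Snx1 (0.55 ± 0.16), B3galt6 (0.996 ± 0.30), Ccn5 (0.85 ± 0.27) and Slit2 (at least 1.03-fold, not above background on any vehicle array). Those lower were Syne1 (-2.29 ± 0.58), Prss38 (-0.52 ± 0.14), Lca5 (-0.68 ± 0.19) and, not above background on any 4b array, Csf3 (at least 1.34-fold) and Hoxb3 (at least 1.22-fold), all at an adjusted p of 1 in limma.

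8 lists were called in wild-type mice without a single called member. Extracellular matrix genes had a median of 0.43 (camera adjusted p = 7.91e-09, and adjusted p = 0.529 with an estimated correlation). Lipid synthesis genes had a median of 0.45 (camera adjusted p = 2.01e-07, and adjusted p = 0.529 with an estimated correlation). Their score was 1.64 and 1.22 on WT_4b replicates 1 and 3 and -0.08 to 0.08 on the other 3. Replicates 1 and 3 also had the high adipocyte scores (2.48 and 2.03, others -0.54 to -0.25) and lymphocyte scores (2.74 and 1.31, others -0.97 to -0.63), while the adipocyte list, with a median of 0.60, was not called (camera adjusted p = 0.164). Leukocyte markers stood at 0.65 (camera adjusted p = 1.71e-06, and adjusted p = 0.691 with an estimated correlation). Slow fibre genes stood at 0.57 (camera adjusted p = 5.4e-06, and adjusted p = 0.529 with an estimated correlation). Interferon response genes had a median of 0.29 (camera adjusted p = 0.00252, and adjusted p = 0.828 with an estimated correlation), with scores of 0.66 and 0.47 on replicates 1 and 3 and 0.04 to 0.07 on the others. Smooth muscle markers stood at 0.28 (camera adjusted p = 0.00557, and adjusted p = 0.529 with an estimated correlation). Tendon markers stood at 0.46 (camera adjusted p = 0.0213, and adjusted p = 0.714 with an estimated correlation). Genes of excitation-contraction coupling had a median of -0.14 (camera adjusted p = 0.0391, and adjusted p = 0.925 with an estimated correlation). In each of these lists 0 genes passed adjusted over the list alone, and fry called 0 lists. Among members with the smallest p, none passing, were the protease inhibitor gene Timp1 (0.99 ± 0.41 SE), the ATP citrate lyase gene Acly (1.20 ± 0.57), the monocyte receptor gene Cd14 (1.03 ± 0.40), Sln (0.86 ± 0.41), Oasl2 (0.80 ± 0.32), the smooth muscle actin gene Acta2 (0.58 ± 0.30), Mkx (0.49 ± 0.31) and Kcnj2 (-0.35 ± 0.19). Without the 6 arrays of high lymphocyte score the lipid synthesis call was lost (adjusted p = 0.108), and the interferon call was lost under 6 of 34 alternatives, among them without these arrays (0.139), without WT_4b replicate 1 (0.0792) and without WT_vehicle replicate 1 (0.276). Calls were also lost under 1 of 34 alternatives for slow fibre genes (without the 6 arrays, 0.0757) and for leukocyte markers (without WT_vehicle replicate 1, 0.251). For excitation-contraction coupling the call was lost under 12 of 34, among them without WT_vehicle replicates 1 (0.531), 2 (0.195) and 3 (0.0714) and WT_4b replicates 1 (0.37) and 3 (0.127). For smooth muscle markers it was lost under 5 of 34, with WT_vehicle replicate 2 (0.157) and WT_4b replicate 2 (0.0664) left out, and for tendon markers under 6 of 33, with WT_vehicle replicates 1 (0.276) and 4 (0.111) and WT_4b replicates 2 (0.229) and 4 (0.172) left out.

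In transgenic mice, Nfkbib, which encodes an inhibitor of NF-kappaB, was at 7.91 ± 0.23 (SD, n = 3) with 4b and 6.84 ± 0.18 (SD, n = 4) with vehicle, a 2.11-fold difference (log2 1.08 ± 0.16 SE, limma adjusted p = 0.0477). It was the single gene called of 10295, and its call was lost under 24 of 36 alternatives, 12 of them the omission of 1 array, always with the same sign. In all, 1517 genes had an unadjusted p under 0.05 against 515 on average by chance. Genes move together and the spread was pooled over all groups, so this excess does not exclude chance. Of the other divisions of the transgenic arrays, 8 also called genes, up to 1201. Genes of muscle breakdown lay higher as a list, but the groups overlapped. The atrophy score ran from 0.853 to 1.191 on the arrays with 4b and from 0.13 to 0.927 on those with vehicle. The atrophy list shifted up by a median of 0.50 with 0 of 26 genes called (7 higher adjusted over the list alone, camera adjusted p = 6.32e-06, and adjusted p = 0.48 with an estimated correlation). The autophagy kinase gene Ulk1 was at 1.16 ± 0.19 (SE), the cathepsin gene Ctsl at 1.30 ± 0.33, Fbxo31 at 1.19 ± 0.34 and Gabarapl1 at 1.20 ± 0.37.

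The proteasome list shifted up by a median of 0.29 (1 of 26 higher adjusted over the list alone, Psmc2 at 0.64 ± 0.17, camera adjusted p = 3.64e-05, and adjusted p = 0.638 with an estimated correlation). The glucocorticoid list shifted up by 0.69 (3 of 16 higher adjusted over the list alone: Foxo1 at 1.09 ± 0.33, Per1 at 1.12 ± 0.36 and Mt2 at 1.52 ± 0.51, camera adjusted p = 0.000309, and adjusted p = 0.638 with an estimated correlation). The list of myogenic regulators shifted down by a median of -0.49 (2 of 15 lower adjusted over the list alone: Mef2c at -1.38 ± 0.22 and Myf6 at -1.28 ± 0.33, camera adjusted p = 0.000364, and adjusted p = 0.322 with an estimated correlation). Oxidative phosphorylation shifted down by -0.15 (0 of 45 adjusted over the list alone; Sdhc at -0.39 ± 0.16 and Cox6c at -0.50 ± 0.20 did not pass, camera adjusted p = 0.00318, and adjusted p = 0.699 with an estimated correlation). Its score was -0.42, -0.08 and 0.08 on the 3 arrays with 4b, and without Tg_4b replicate 1 the call was lost (-0.02, adjusted p = 0.581), as was that of excitation-contraction coupling (-0.21, adjusted p = 0.102). Excitation-contraction coupling shifted down by -0.46 (2 of 18 lower adjusted over the list alone, Stac3 at -0.74 ± 0.21 and Asph at -1.27 ± 0.36, camera adjusted p = 0.00318, and adjusted p = 0.638 with an estimated correlation). Tendon markers shifted by -0.76 (1 of 7 lower adjusted over the list alone, Scx at -1.39 ± 0.41, camera adjusted p = 0.00537, and adjusted p = 0.638 with an estimated correlation). Fry called 1 list.

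The count was 421 without Tg_4b replicate 3, 325 without Tg_vehicle replicate 1, 4 without Tg_vehicle replicate 3, 2 without WT_4b replicate 1, 1 without Tg_vehicle replicate 2, and 0 without any 1 of the other 11 arrays. Array weights called 1778 genes. The lymphocyte score was 1.45 and 1.16 on Tg_4b replicates 1 and 2 and -0.94 on replicate 3. Without the 6 arrays of high lymphocyte score, which left 1 transgenic 4b array, only the myogenic list kept its call of the 7, while the atrophy (adjusted p = 0.0741), glucocorticoid (0.0843), proteasome (0.972) and tendon (0.685) calls were lost and the other 2 turned.

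The response to 4b differed between genotypes for 0 genes (1039 at an unadjusted p under 0.05; the ordinary test without moderation also called 0). The smallest p-values belonged to Nfkbib (1.38 ± 0.21 SE, limma adjusted p = 0.0711), Ulk1 (1.31 ± 0.26), Gfer (0.82 ± 0.18), Cstf1 (0.93 ± 0.21) and Ttc24 (1.16 ± 0.26) on the side higher in transgenic mice. On the lower side they belonged to the muscle transcription factor gene Mef2c (-1.32 ± 0.29), Cul7 (-1.15 ± 0.26), Lurap1l (-1.77 ± 0.40), Ptprd (-1.35 ± 0.31) and the T cell gene Cd28 (-1.85 ± 0.43), and none passed. Camera called 12 lists for this difference, whose medians stand among the results singled out after the report, and 0 held with an estimated correlation (lowest adjusted p = 0.441 with an estimated correlation). Array weights called 89 genes, 17 were called without Tg_4b replicate 3 and 1 without Tg_vehicle replicate 1.

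Among mice given 4b, transgenic muscle had 20.9-fold more of the cell cycle inhibitor gene Cdkn1a than wild-type muscle: 13.35 ± 0.60 (SD, n = 3) against 8.96 ± 0.80 (SD, n = 5; log2 4.39 ± 0.66 SE, limma adjusted p = 0.000591). The collagen genes Col1a1 and Col5a1 fell, and the cathepsin gene Ctsl, the proteasome gene Psmc2 and the acyl-CoA dehydrogenase gene Acadl rose. In all, 2911 genes were called, 1597 higher and 1314 lower, 1221 of them by over 2-fold. With median scaling, which moved the median of all genes from -0.0045 to 0.11, the split was 2375 higher and 846 lower.

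The other large rises were Sln (19.4-fold), the mTORC1 inhibitor gene Ddit4 (14.3-fold), the glycine methyltransferase gene Gnmt (14.3-fold), the glucocorticoid-induced Fkbp5 (12.9-fold), the acyl-CoA thioesterase genes Acot1 (12.3-fold) and Acot2 (9.25-fold), the calprotectin subunit gene S100a8 (11.4-fold), Slc10a6 (10.3-fold), Tfdp2 (9.60-fold), Slc25a34 (9.49-fold) and Doc2b (at least 7.24-fold, since no wild-type 4b array was above background). The largest falls were Col1a1 (31-fold, detected on 1 of 3 transgenic arrays), Nrep (28.4-fold), the integrin gene Itgb6 (26.1-fold), the lumican gene Lum (15.7-fold), the fast fibre calsequestrin gene Casq1 (15.5-fold), Gdap1 (15.4-fold), Ky (14.7-fold) and Rsph1 (11.7-fold). Mup2, the pleiotrophin gene Ptn, Col6a2 and Col3a1 were not above background on any transgenic 4b array and were at least 8.33-fold, 8.97-fold, 7.84-fold and 7.09-fold lower. Adjusted p in limma was at most 0.0192 (Mup2) over these genes. The log2 change of Col1a1 was -4.955 and as small as -3.28 over the alternatives. Hdac1 (-0.57 ± 0.20 SE, limma adjusted p = 0.048), Hdac3 (-0.45 ± 0.15, adjusted p = 0.0393) and Prnp (0.50 ± 0.17, adjusted p = 0.0407) passed narrowly, and their calls were lost under 18, 13 and 11 of 36 alternatives, with Hdac3 at -0.07 without the 6 arrays of high lymphocyte score.

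Of 26 atrophy genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone). Leading were Ctsl, Eif4ebp1, Foxo1 and Ulk1 (camera adjusted p = 6.07e-06, and adjusted p = 0.651 with an estimated correlation). Of 23 matrix genes, 13 fell (14 adjusted over the list alone). At their head were Col6a2, Col1a1, Col5a1 and Col15a1 (camera adjusted p = 2.19e-07, and adjusted p = 0.651 with an estimated correlation). Of 26 proteasome genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.000762, and adjusted p = 0.679 with an estimated correlation), with Psmc2, Psmd11, Psmd4 and Psmb3 leading. Of 27 genes of PGC-1 and fatty acid oxidation, 12 rose and 1 fell (12 and 1 adjusted over the list alone), led by Acadl, Etfdh, Acadvl and Slc25a20 (camera adjusted p = 0.000664, and adjusted p = 0.651 with an estimated correlation). Of 16 glucocorticoid response genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), led by Foxo1, Ddit4, Mt2 and Mt1 (camera adjusted p = 0.00241, and adjusted p = 0.651 with an estimated correlation).

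Fast fibre genes (6 of 17 lower, 1 higher, the same counts adjusted over the list alone, camera adjusted p = 0.00532, and adjusted p = 0.651 with an estimated correlation) shifted down. So did excitation-contraction coupling (8 of 18 lower, also 8 adjusted over the list alone, camera adjusted p = 0.00273, and adjusted p = 0.711 with an estimated correlation) and glycolysis (8 of 19 lower, 11 adjusted over the list alone, 1 higher, camera adjusted p = 0.00532, and adjusted p = 0.711 with an estimated correlation). Among them were Casq1, Gpd1, Camk2a, Jph2, Pgm1 and Phka1. Tendon markers (5 of 7 lower, 5 adjusted over the list alone, camera adjusted p = 0.00402, and adjusted p = 0.651 with an estimated correlation) shifted down. Interferon response genes (4 of 18 lower, 1 adjusted over the list alone, Oasl2, camera adjusted p = 0.00874, and adjusted p = 0.711 with an estimated correlation) did too. Lipid synthesis genes (2 of 18 lower, Srebf1 and Fdps, 2 adjusted over the list alone, camera adjusted p = 0.0311, and adjusted p = 0.711 with an estimated correlation) shifted down as well. With 4b the adipocyte score averaged 0.66 ± 1.47 (SD, n = 5) in wild-type and -0.11 ± 0.84 (SD, n = 3) in transgenic mice. The leukocyte score averaged 0.64 ± 0.50 and -0.04 ± 0.715 (SD) in the same groups. Ribosomal protein genes shifted up (2 of 26 higher, Rpl19 and Rps9, 0 adjusted over the list alone, camera adjusted p = 0.0489, and adjusted p = 0.74 with an estimated correlation). The ribosomal call was lost under 16 of 34 alternatives, with an adjusted p of up to 0.27 without Tg_4b replicate 1, and the lipid synthesis call under 9 of 34, among them without WT_4b replicates 1 (0.128) and 3 (0.0807) and Tg_4b replicate 3 (0.0698). Without the 6 arrays of high lymphocyte score the lipid synthesis (0.518), ribosomal (0.247), proteasome (0.449), glycolysis (0.518) and fast fibre (0.101) calls were lost. Fry called 11 lists, among them the p53 response (fry adjusted p = 4.38e-05) and polyamine metabolism (fry adjusted p = 0.0233), which camera did not call. The count of 2911 fell to 1618 without Tg_4b replicate 1 and 1577 without Tg_4b replicate 2, rose to 4768 with array weights, and was 4 without the 6 arrays of high lymphocyte score, which left 1 transgenic 4b array, assumed to vary like the other groups.

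**Figure D3:**
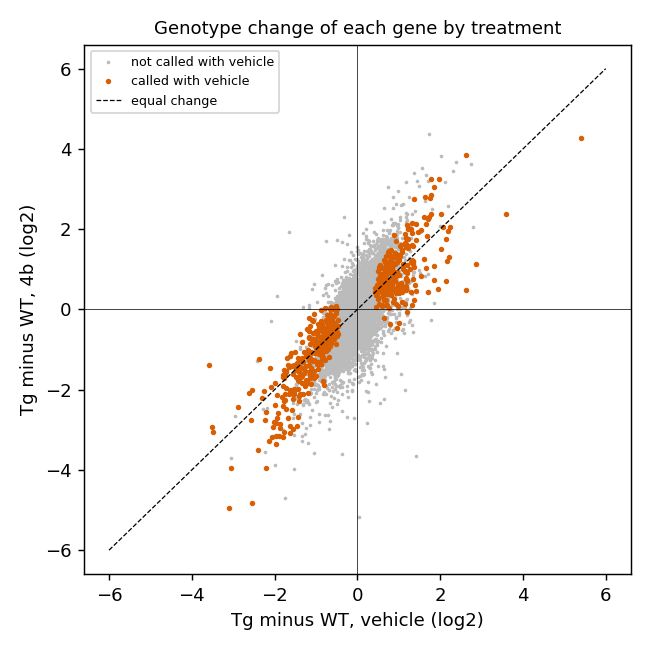
Log2 difference between transgenic and wild-type mice for each tested gene with vehicle (x axis) and with 4b (y axis); orange points are the 546 genes called with vehicle, grey points the others, and the dashed line marks equal change. Of the 546, 536 had the same sign with 4b.

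Of the 546 genes called with vehicle, 425 were also called with 4b, 178 higher and 247 lower in both, where independent lists would share 38.2 and 38.3. The comparisons share no array. Over the 546 genes the slope of the genotype effect with 4b on that with vehicle was 1.03 ± 0.143 (jackknife SE over arrays). Over all genes it was 1.10 ± 0.234, and 0.864 without WT_vehicle replicate 4. Over the genes called with 4b, the effect with vehicle had a slope of 0.505 ± 0.172 on the effect with 4b. Picking genes by 1 comparison shrinks the other. The 4b effects in wild-type and transgenic mice had a Pearson correlation of -0.0527 and a Spearman correlation of -0.0933 across genes, which are not independent replicates. The Pearson value had a jackknife SE over arrays of 0.181 and ran from -0.137 to 0.0897 with each array left out. In 100 simulations of unchanged groups this correlation ran from -0.758 to 0.524. A value near 0 therefore cannot tell whether 4b moved the same genes in both genotypes.

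Genes changed by genotype and by 4b in transgenic mice were compared for reversal. Of the 546 genes, 201 moved with 4b against the genotype difference, 345 moved with it, and 0 passed for 4b. The covariance of the 2 effects across genes was 0.05 ± 0.0348 (jackknife SE over arrays). In 100 simulations of unchanged groups sharing the same transgenic vehicle arrays it was -0.0563 on average (-0.145 to 0.0151), a difference of 0.106. The simulated groups had no genotype difference. Their range therefore cannot show how a chance division of transgenic animals that differ among themselves moves the covariance, and chance is not excluded. With the transgenic vehicle arrays split 2 and 2 between the contrasts the covariance was 0.0284 to 0.216 over 6 splits. It turned to -0.0286 without the 6 arrays of high lymphocyte score, and was 0.0194 and 0.0249 without Tg_vehicle replicates 4 and 1, 0.0811 without Tg_4b replicate 3, 0.0307 without background correction and 0.0261 without a filter on dim probes.

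Averaged over genotypes, 4b changed 0 genes (834 at an unadjusted p under 0.05 in limma; 0 in the ordinary test without moderation). Rab6b (1.71 ± 0.36 SE), Sema5a (1.63 ± 0.34), Mrps6 (0.50 ± 0.11), Bet1l (0.53 ± 0.12) and Gzmm (0.65 ± 0.15) on the higher side had the smallest p without passing. On the lower side these were Prss38 (-0.55 ± 0.11), Mef2c (-0.72 ± 0.14), Dffa (-0.75 ± 0.16), Prkg1 (-0.69 ± 0.16) and Abhd16a (-0.81 ± 0.19), and all had the same adjusted p (limma, adjusted p = 0.477). Array weights called 222 genes, 11 were called without Tg_4b replicate 3 and 1 without Tg_vehicle replicate 1. Averaged over treatments, genotype changed 3420 genes, 1838 higher and 1582 lower in transgenic mice (2736 and 985 with median scaling, which moved the median of all genes from -0.0031 to 0.10). Igfbp3 (5.48-fold), the interleukin-6 receptor gene Il6ra (4.83-fold) and the cold-inducible RNA-binding protein gene Cirbp (4.04-fold) rose and were not among the genes named above. The largest changes were Sln (28.6-fold higher, limma adjusted p = 6.13e-07) and Col1a1 (16.3-fold lower, adjusted p = 3.05e-05). Col1a1 was dim in transgenic mice, and its log2 change ran from -4.31 to -2.67 over the alternatives. Camera called 12 lists for genotype and 11 for 4b, 0 of them with an estimated correlation (lowest adjusted p = 0.617 and 0.388 with an estimated correlation).

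**Figure D4:**
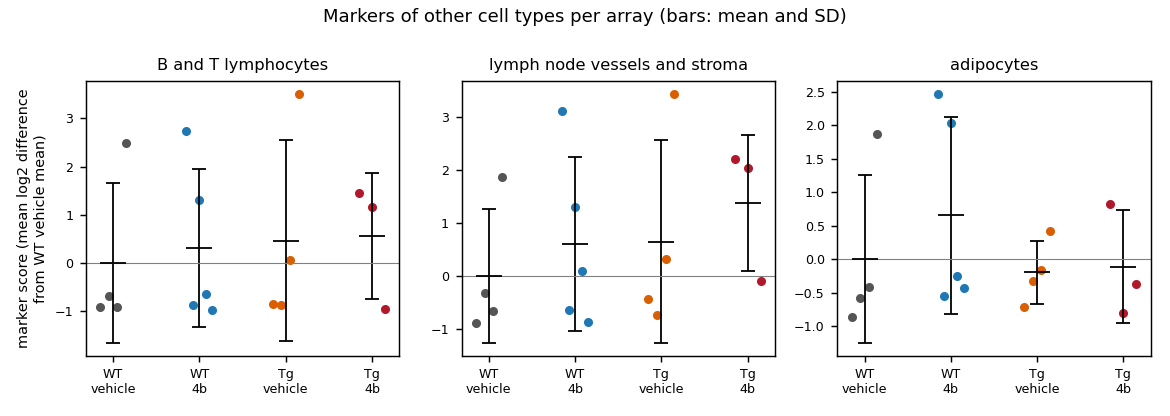
Marker scores of lymphocytes, lymph node vessels and stroma, and adipocytes on each array (y axis, mean log2 difference from the mean of wild-type mice given vehicle) by group (x axis); points are arrays and bars the mean and SD. The lymphocyte score ran from -0.97 to 3.51 and was high on some arrays of every group.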

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

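The tests of sex, of lymphocyte and adipocyte scores, of the share of probes detected, of lymph node markers and of exchanged labels were chosen after the result was seen; the counts over other divisions of the arrays and the test of a single animal were planned. Of 222 groups of 4 or 5 arrays, 13 held an array far from the others of its group, where chance gives 11.1.

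WT_4b replicate 1 had an Ankrd2 level of 9.94 log2 units (others 10.88 to 11.11) and an oxidative phosphorylation score of -0.21 (others 0.05 to 0.09). WT_4b replicate 4 had a Col1a1 level of 12.48 (others 9.35 to 10.10), a Cdkn1a level of 10.35 (others 8.35 to 8.82) and an extracellular matrix score of 1.35 (others 0.13 to 0.44). WT_4b replicate 5 had a slow fibre score of -0.42 (others 0.60 to 0.99). Among wild-type mice given vehicle, replicate 1 had a Chrna9 level of 6.56 (others 5.39 to 5.57), and replicate 4 a Cyp2f2 level of 10.29 (others 7.17 to 7.62) and a lymphocyte score of 2.49 (others -0.91 to -0.68). Among transgenic mice given vehicle, replicate 1 had an S100a8 level of 11.15 (others 8.13 to 8.39) and a Ky level of 9.46 (others 12.31 to 12.49), replicate 3 a Myl6b level of 5.96 (others 7.36 to 7.62) and replicate 4 a Mup2 level of 6.87 (others 4.53 to 4.81).

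The response to 4b differed between genotypes for 12 gene lists by camera at the preset correlation, and for 0 with an estimated correlation. The median difference, transgenic minus wild type, was 0.61 for muscle atrophy, 0.68 for the glucocorticoid response and 0.31 for the proteasome. It was -0.44 for slow fibre genes, -0.69 for myogenic regulators, -0.17 for oxidative phosphorylation, -0.50 for lipid synthesis, -0.63 for the interferon response and -0.86 for extracellular matrix. For cell markers it was -0.76 for macrophages and other leukocytes, -0.40 for smooth muscle and -1.17 for tendon. The oxidative phosphorylation call was lost without Tg_4b replicate 1 (adjusted p = 0.303) and the lipid synthesis call without WT_4b replicate 1 (0.0682). The leukocyte call failed under 13 of 34 alternatives, 1 of them a reversal, and among them without WT_vehicle replicates 1 (median -0.20) and 2 (adjusted p = 0.0668), WT_4b replicate 1 (0.0906), Tg_vehicle replicate 4 (0.534) and Tg_4b replicate 3 (0.447). The slow fibre call was lost under 7 of 34, among them without Tg_vehicle replicates 1 (0.122) and 4 (0.144) and WT_vehicle replicates 3 (0.052) and 4 (0.088). The glucocorticoid call was also lost under 7 of 34, among them without Tg_vehicle replicate 2 (0.0572), Tg_4b replicate 1 (0.0739) and WT_vehicle replicate 4 (0.113). The interferon call was lost under 6 of 34, among them without Tg_vehicle replicate 4 (0.0575). Leaving out the 6 arrays of high lymphocyte score left 1 transgenic 4b array. The calls of oxidative phosphorylation, lipid synthesis, slow fibre genes and the proteasome were then lost. So were those of the glucocorticoid response, the interferon response and muscle atrophy.

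The genotype difference stood apart from other divisions of the arrays. The real division called 546 genes with vehicle, and it was 1 of 35 with as many (highest other 0). With 4b it called 2911 and was 1 of 56 (highest other 8). Averaged over treatments it called 3420 and was 1 of 100 drawn (highest other 1). Each is the smallest share its divisions can give, so chance is unlikely for these counts but not excluded. Of the 3420 genes, 3260 remained called with sex as a covariate and 3272 with the share of probes detected. This argues against either as the whole source of the difference averaged over treatments. Of the 546 genes called with vehicle, fewer held: 419 with sex, 509 with the share of probes detected and 378 with both. All 546 kept their sign. With lymphocyte and adipocyte scores as covariates 2639 of the 3420 genes remained called and all 3420 kept their sign. Whether tissue next to the muscle contributes to the genes that lost their call stays open, since the covariates also leave fewer degrees of freedom. The transgene stays a hypothesis for the difference, with other differences between the animals' parents untested.

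Lymphocyte markers were high on some arrays of every group, from -0.97 to 3.51. The score of lymph node vessels and stroma rose with it over the 16 arrays, Pearson r = 0.968, permutation p = 1e-05, adjusted p = 4e-05; Spearman rho = 0.906, permutation p = 1e-05, adjusted p = 4e-05, the smallest p the permutations can give. It was r = 0.938 without the 2 arrays farthest from the median. Both lists were written after the data were seen, so their correlation and its p cannot test where the markers came from. Pieces of lymph node in the sample are a candidate explanation. Among the 4 relations tested, the macrophage score showed r = 0.307 (permutation p = 0.248, adjusted p = 0.248) and rho = 0.176 (p = 0.511, adjusted p = 0.511), r = 0.272 without the 2 arrays, while adipocyte markers showed r = 0.754 (p = 0.00197, adjusted p = 0.00263) and rho = 0.641 (p = 0.00902, adjusted p = 0.0155), r = 0.793 without them. The share of probes detected rose with the lymphocyte score too, r = 0.767 (p = 0.00044, adjusted p = 0.00088) and rho = 0.624 (p = 0.0116, adjusted p = 0.0155), r = 0.579 without them, so it is not a measure apart from that score. The high levels on WT_4b replicate 1 reached 13.10 log2 units for Glycam1, a product of lymph node vessels, and 10.23 for the B cell gene Cd79b. Neither genotype (0.35, exact permutation within treatments, p = 0.701) nor 4b (0.20, exact permutation within genotypes, p = 0.825) was told apart from no difference with so few arrays, and neither is thereby excluded.

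Over all genes the genotype effect with 4b had a slope of 1.10 ± 0.234 (jackknife SE over arrays) on that with vehicle. The slope was not told apart from 1, so a greater distance from wild type with 4b was not shown. A single animal may account for a slope above 1, since it was 0.864 without WT_vehicle replicate 4. Of the 35 divisions of the 7 transgenic arrays, 2 gave as large a slope (highest other 1.22), so chance cannot be excluded. For 4b in transgenic mice, 9 of 35 divisions called at least the real 1 gene and the highest other called 1201, so chance cannot be excluded for this count. The 1201 point to a structure among the transgenic animals: that division exchanged Tg_vehicle replicate 1 with Tg_4b replicate 3. An exchange of these 2 labels could give this, as could animals differing in severity. Some values ran with the labels. The myogenic score was -0.33 on Tg_4b replicate 3 (others with 4b -0.52 and -0.43) and 0.41 on Tg_vehicle replicate 1 (others 0.03 to 0.75). Prnp was 14.11 on the former and 14.55 on the latter. The myogenic list was called for 4b under these same labels, so its score cannot weigh against an exchange. Other values ran with an exchange only in part. On Tg_vehicle replicate 1 and Tg_4b replicate 3 the glucocorticoid score was 1.40 and 1.21, the atrophy score 0.93 and 0.85, and Cdkn1a 13.22 and 12.65. The other vehicle arrays had 0.12 to 0.87, 0.13 to 0.61 and 9.99 to 11.16 in this order. The other 4b arrays had 1.42 and 1.69, 1.17 and 1.19, and 13.67 and 13.71. Each time Tg_vehicle replicate 1 lay near the other 4b arrays. Tg_4b replicate 3 lay above the other vehicle arrays and below the other 4b arrays. The exchange stays open, and the labels were kept as given. For 4b in wild-type mice, the difference between genotypes and 4b averaged over genotypes the real count was 0. Every one of the 100 drawn divisions must then call as many, so the comparison decides nothing. The highest other counts were 14, 568 and 252.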

How the results depend on the processing

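Sex, lymphocyte and adipocyte scores, the share of probes detected and the omission of 3 or 6 arrays of high lymphocyte score were tried after the data had been seen; all other settings were planned. Of the named genes called, 2595 values under alternatives stayed called with the same sign and 188 fell short of the threshold; of the called lists, 2195 stayed, 241 fell short and 6 reversed. The cause of the changes below was not tested, except that settings with fewer arrays test with fewer animals.

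Genes changed by genotype with vehicle (546) were 124 with only the groups compared, 880 with array weights, 0 without moderation of the variance, 222 without the 2 animals numbered in 3 digits and 1049 with the share of detected probes, and 175 to 665 with each array left out. Genes changed by 4b in transgenic mice (1) were 4 without background correction and with the authors' deposited values, 3 with an offset of 50, cyclic loess or probes detected on all 16 arrays, 1778 with array weights, 4 with lymphocyte and adipocyte scores, 2 without 6 arrays and 0 to 421 with each array left out. They were 0 with median scaling, all detected probes, only the groups compared, no moderation, the assumed chip, without the 2 animals numbered in 3 digits, without 3 arrays, and with sex, the detected share or both. Genes whose response differed between genotypes (0) were 1 without a filter, with probes detected on all 16 arrays and without 6 arrays, 89 with array weights and 0 to 17 with each array left out. Genes changed by genotype with 4b (2911) were 4768 with array weights, 4 without 6 arrays and 1577 to 3098 with each array left out. Averaged over genotypes, 4b (0) gave 222 with array weights, 1 without 6 arrays and 0 to 11 with each array left out; averaged over treatments, genotype (3420) gave 1127 without 6 arrays and 2670 to 3597. The count for 4b in wild-type mice stayed 0 under every alternative run. Omission of the 6 arrays left 1 transgenic 4b array, assumed to vary like the other groups.

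The slope of 1.03 was 0.741 without 6 arrays, 0.505 over the genes called with 4b and with the regression turned and 0.915 to 1.15 with each array left out. The correlation of the 4b effects ran from -0.137 to 0.0897 with each array left out. The reversal covariance of 0.05 was -0.0286 without 6 arrays, 0.150, 0.216 and 0.159 with transgenic vehicle arrays 1 and 2, 1 and 3, or 1 and 4 in the genotype contrast, and 0.0194 to 0.0811 with each array left out. The 72 list shifts were 0 with an estimated correlation, 32 by fry and 65 to 74 with each array left out. The genotype change of Prnp averaged over treatments ran from 0.76 to 0.90 with each array left out, and from 0.76 to 1.02 over all 35 alternatives. The leukocyte list reversed to 0.11 for the difference between genotypes with the detected share and sex. Without 6 arrays, oxidative phosphorylation (0.054) and excitation-contraction coupling (0.065) reversed for 4b in transgenic mice, and oxidative phosphorylation (0.051), glycolysis (0.025) and the proteasome (0.01) for 4b averaged over genotypes. No paired analysis was possible because replicate numbers were given in order of deposit and pair no animals. Signal over background limits dim genes, whose changes the offset compresses.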

Other observations

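The test of the strain region around Prnp was planned; that of the transgene was chosen after the result was seen. Among gene lists fixed before the data were examined that camera did not call for genotype with vehicle, genes of the histone deacetylases and sirtuins had a median of -0.01 (1 of 14 higher, camera adjusted p = 0.968) and the histone and class I histone deacetylase inhibitor response genes -0.22 (1 of 14 lower, camera adjusted p = 0.199). Fry, which compares a list with no change and not with other genes, did call the latter (fry adjusted p = 0.00898). For 4b in wild-type mice these response genes had a median of -0.07 (camera adjusted p = 0.546), and for 4b in transgenic mice 0.17 (camera adjusted p = 0.137), with 0 of 14 genes called in either and no call by fry (lowest fry adjusted p = 0.053). In transgenic mice their score ran from 0.071 to 0.253 with 4b and from -0.337 to 0.007 with vehicle, without overlap. In wild-type mice it ran from -0.166 to 0.091 and from -0.135 to 0.168, with overlap. Heat shock protein genes had 2 of 14 higher for genotype with vehicle (camera adjusted p = 0.363), and circadian clock genes 6 of 14 higher and 2 lower for genotype with 4b (camera adjusted p = 0.432).

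The Prnp probe was higher on all 7 transgenic arrays than on every wild-type array. RNA of the transgene read by the Prnp probe may give this, since the construct carries prion promoter sequence, but no value here separates it from a change of the mouse gene itself. A strain difference in the chromosome region around Prnp is another candidate explanation. The 20 nearest tested genes on chromosome 2 had a median genotype change of -0.11 (log2) against 0.83 for Prnp, which was the value set in advance against a regional difference. That bound was wrong by design, because alleles of a strain region need not move each gene the same way or by the change of Prnp, so a median decides nothing. Of the 20, 9 were called, 4 higher and 5 lower, where 33.2% of all tested genes were called, so the count shows no regional effect either and the region stays open.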
